A study of Mus musculus with 4 samples.

How the data were processed

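Total RNA of mouse back skin had been extracted with Trizol and column purification and converted to biotin-labelled cRNA from 5 micrograms per array, per the labels' protocols. The deposited values are RMA expression values per the submitters' processing notes, which name no version; RMA corrects background, normalizes probes by quantiles and summarizes them per probe set. The notes do not name a log base. The values of 2.65 to 14.7 with array medians near 7 are the range of log2 RMA values, and the deposited values were used as log2 without further normalization. The table held 45101 probe sets on 4 arrays. Software, genome build and annotation of the authors' processing are not given in the sources used here, so no coordinates are printed. Scanner files and detection calls were not analysed here.

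Samples were grouped by their labels as wild type (n = 2 arrays) and K5-IKKbeta transgenic (n = 2 arrays). Each array is a pool of 3 mice; p-values measure the spread between pools, and the spread between single mice cannot be seen. No scan date or batch was given in the sources used here. The number of arrays limits the precision.

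Probe sets were named from the annotation of the array platform, with symbols updated through gene identifiers of the RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. Of the probe sets, 34958 had 1 symbol, 932 several and 9211 none; 34754 matched the gene table by identifier and 0 symbols changed. Probe sets with several symbols or none named no gene. For each of 18194 genes the probe set with the highest mean over the 4 arrays was used, and genes whose probe set had a mean above the 40th percentile of all probe sets (6.33 on the log2 scale) were tested, which left 13074 genes and removed 5120.

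The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05; the prior had 4.00 degrees of freedom beside 2 residual ones. At an unadjusted p under 0.05, 5775 genes passed. The median log2 fold change of all tested genes was 0.09 and that of all probe sets 0.00. Fold changes are 2 to the power of the absolute log2 fold change. Where both arrays of the dimmer group lay below the 25th percentile of their array's probe sets, the fold is given as at least the brighter group's mean over that floor, a choice made after the data were examined; 22 changed genes had a group below this floor. RMA compresses large changes, and values near the top of the range may be held down by saturation, so folds of the brightest genes are rough.

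Gene lists for skin cell types, follicle parts, leukocytes and pathways (40 lists) were fixed before the data were examined, as were groups, tests and alternative settings. They held 826 different symbols, of which 737 had a probe set of 1 gene and 633 were tested; the others, Isg15, Nfkb1 and C3 among them, were not analysed here. Lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. They were also tested with camera at an estimated correlation and with fry. At an estimated correlation camera takes its test on the 2 residual degrees of freedom and has little power whatever the correlation. For each list the count of members past the threshold is given over all genes and adjusted over the list alone. Some genes are in more than 1 list.

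Genes were named by a rule fixed before the data were examined: Ikbkb; the 12 higher and 12 lower genes with the largest log2 fold change among those past the threshold with no overlap between the groups' arrays; and for each list up to 4 members past the threshold with the largest fold change, or up to 2 with the smallest p where none passed. Other genes are said to have been picked after their values were seen, or were named because they are few.

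The procedure was tested on simulated data for 13074 genes, with spreads drawn from limma's prior and a seeded set of genes changed. It recovered 8 of 67 genes changed 1.5-fold (11.9%), 53 of 67 changed 2-fold (79.1%) and 65 of 66 changed 4-fold (98.5%). There were 7 false calls among 133, and 2 of 2 shifted lists were called and 0 others. Simulated genes varied independently, and a far smaller share of them changed than the 33.9% called in the data. The simulation therefore does not test camera on correlated genes, and the correlation estimated for interferon-stimulated genes in the data was 0.86.

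Alternatives were no filter on dim probe sets, a filter at the 60th percentile, the mean of all probe sets of a gene, probe sets with an ending that marks shared sequence left out, another quantile normalization, centring each array on its median, eBayes with a trend and robust settings, no moderation across genes, a test against a 1.2-fold change (treat), the replicate number as a block, each array left out in turn, and the list tests above. Leaving out the hair genes before a new quantile normalization was added after the data were seen. Labels number the arrays 1 and 2 in both groups but do not say that a number pairs them, so the arrays were not paired.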

Results

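RNA of mouse back skin was measured on 4 Affymetrix arrays, 2 of wild type skin and 2 of skin from K5-IKKbeta transgenic mice. These mice carry the gene of IKKbeta, the kinase (gene symbol Ikbkb) that activates the transcription factor NF-kB, under regulatory elements of keratin K5, which is made by basal keratinocytes of epidermis and hair follicle. All mice were 32-day-old males, and each array held a pool of RNA from 3 mice of its genotype, so the spread between arrays of a group is a spread between pools. Median log2 expression over all probe sets was 6.92 and 6.91 in the wild type arrays and 6.96 and 6.95 in the K5-IKKbeta arrays. Over all probe sets, Pearson's correlation was 0.996 between the wild type arrays, 0.994 between the K5-IKKbeta arrays and 0.965 to 0.969 between arrays of different genotype; these are correlations across probe sets, which are not independent replicates. Log2 fold changes are K5-IKKbeta minus wild type throughout, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

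The gene of the transgene was checked first. Of 5 probe sets for Ikbkb, 3 were higher in K5-IKKbeta skin and 2 did not differ past the threshold. Probe set 1454184_a_at went from 6.52 ± 0.03 (SD, n = 2) in wild type to 8.76 ± 0.02 (n = 2), a 4.71-fold rise (limma adjusted p = 0.0001 over all probe sets). Probe set 1426333_a_at rose by 0.47 on the log2 scale (adjusted p = 0.029 over all probe sets). The brightest, 1426207_at, which stands for the gene elsewhere in the text, went from 9.78 ± 0.15 to 10.29 ± 0.13 (n = 2 each), a 1.42-fold rise (log2 fold change 0.50, adjusted p = 0.0225 over all genes). Values for 1432275_at and 1445141_at gave log2 fold changes of -0.15 (adjusted p = 0.53) and 0.14 (adjusted p = 0.45). Where each probe set lies relative to the sequence carried by the transgene was not analysed here, and a probe set outside it does not check the genotype. The call of the brightest probe set was lost without wild type 1 (log2 fold change 0.40, adjusted p = 0.15) and without wild type 2 (log2 fold change 0.61, adjusted p = 0.057).

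**Figure D1:**
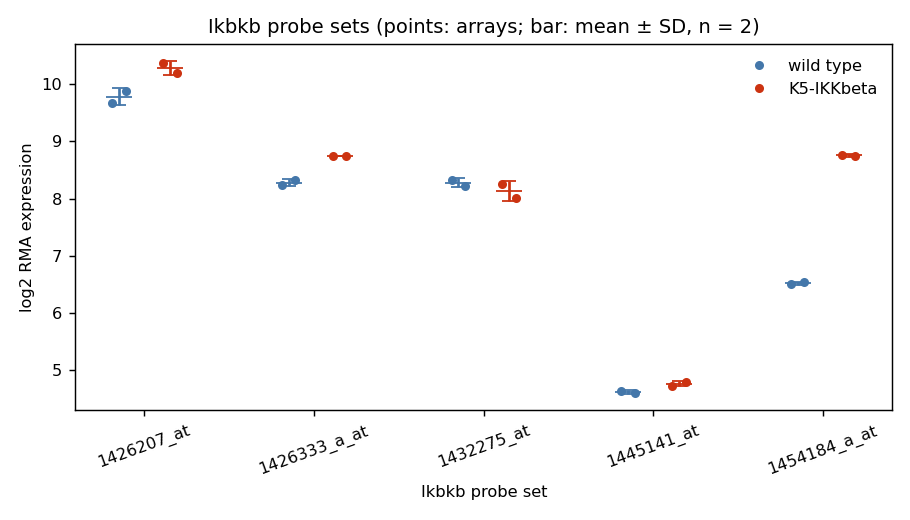
Log2 expression (vertical axis) of the 5 Ikbkb probe sets (horizontal axis) in wild type and K5-IKKbeta skin; points are arrays and bars are mean ± SD (n = 2). The separation is widest for 1454184_a_at, at 6.52 in wild type and 8.76 in K5-IKKbeta skin.

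K5-IKKbeta skin differed from wild type skin in 4436 of 13074 tested genes (33.9%), with 3056 higher and 1380 lower. The largest falls were in genes of the hair shaft, and the rises of the highest fitted size included the peptidoglycan-cleaving enzyme Pglyrp2 and the epidermal keratin Krt2. At least 2-fold changes were found for 780 higher and 441 lower genes. By fitted values, some of them taken against a group near background, 71 genes fell at least 16-fold and 6 rose at least 16-fold. Of those that fell, 46 belonged to the hair shaft or inner root sheath lists or to the Krtap family. Of those that rose, only Pglyrp2, Krt2 and Dscaml1 were at least 16-fold higher by the more careful bounds given below. Arrays of the 2 groups did not overlap for 9081 genes (69.5%), against 33.3% by chance for 2 against 2. With the hair genes left out before a new quantile normalization, a setting added after the data were seen, 2489 genes were higher and 1820 lower. Of changed genes 57.8% were then higher, in place of 68.9%. Another quantile normalization with the hair genes kept gave 59.2%, and centring each array on its median gave 63.9%. Much of this drop thus came without leaving out hair genes. Without wild type 1, 1570 genes were higher and 809 lower, and without wild type 2 these counts were 1584 and 669.

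By fitted log2 fold changes, the highest-ranked rise was in Pglyrp2 (probe set 1420515_a_at), an enzyme that cleaves bacterial peptidoglycan. For it and the next 6 genes both wild type arrays lay near background, so the order of these rises is not established. Pglyrp2 measured 4.48 ± 0.25 in wild type and 10.12 ± 0.33 in K5-IKKbeta skin (n = 2 each), which is at least 27.5-fold higher (adjusted p = 2.1e-05). Folds written as at least were taken against the 25th percentile of all probe sets of an array wherever both arrays of the dimmer group lay below it, since no detection calls were used here. Krt2, a keratin of the upper epidermal layers, was at least 20.9-fold higher, and Ubd, a ubiquitin-like protein that marks others for degradation, was at least 15.7-fold higher. Dscaml1, a cell adhesion molecule of the immunoglobulin superfamily, was at least 16.2-fold higher, and Spib, an Ets transcription factor of lymphoid and dendritic cells, at least 13.9-fold. Crygn, a lens crystallin gene, was at least 13.7-fold higher with a wide spread in K5-IKKbeta skin (9.12 ± 1.10, n = 2), and Bcl2l15, of the Bcl-2 family, was at least 7.51-fold higher. The next 5 rose 9.71-fold to 11.3-fold: Oasl2 of the oligoadenylate synthetase family, the chemokine Cxcl9, the protease inhibitor Stfa3, the peroxisomal thiolase Acaa1b and the chitinase-like protein Chil1.

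By fitted log2 fold changes, the 12 highest-ranked falls were in Krtap genes, whose products form the matrix around keratin filaments of the hair shaft, apart from Gm10228. For 9 of these genes both K5-IKKbeta arrays lay below the floor, so their order, and which genes belong among the 12, are not established. Krtap6-5 measured 14.10 ± 0.00 in wild type and 4.20 ± 0.30 in K5-IKKbeta skin (n = 2 each), at least 441-fold lower (adjusted p = 1.5e-06). Krtap16-3, Krtap19-2, Krtap19-3, Krtap19-1, Krtap14, Krtap19-5 and Krtap6-3 were at least 179-fold to 360-fold lower, and the predicted gene Gm10228 at least 376-fold lower. Krtap15, Krtap19-9b and Krtap21-1, with at least 1 K5-IKKbeta array above the floor, fell with log2 fold changes of -8.94, -8.45 and -8.40. For Krtap15 and Krtap21-1 the other K5-IKKbeta array lay below it (4.89 and 5.14), so these differences are rough. Values of single Krtap genes are uncertain because the family holds near-identical copies to which a probe set can bind in common.

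Hair shaft genes fell as a group. All 28 tested members of the list of hair shaft keratins and keratin-associated proteins were lower, also when adjusted over the list alone (28), with a median log2 fold change of -6.32 (camera adjusted p = 5.5e-38 and adjusted p = 0.40 with an estimated correlation). Over the whole Krtap family, 37 of 37 tested genes fell, with a median log2 fold change of -7.36. Of the list of inner root sheath genes and follicle regulators, 21 of 23 fell (21 lower and 1 higher adjusted over the list alone), with a median of -1.96 (camera adjusted p = 2.4e-16 and adjusted p = 0.40 with an estimated correlation). Krt26 and Krt72, keratins of the inner root sheath, had log2 fold changes of -5.35 and -4.23, S100a3, a calcium-binding protein of the hair cuticle, -4.11, and Padi3, which converts arginines of hair proteins to citrulline, -3.97. Not past the threshold were Gata3, at -0.13 (adjusted p = 0.48), and Shh, the hedgehog ligand made by the growing hair bulb, at 0.32 (adjusted p = 0.099), which passed without K5-IKKbeta 1 (0.46, adjusted p = 0.022). By contrast, of 16 tested markers of follicle stem cells and dermal papilla, 8 were higher and none lower over all genes, and 9 were higher and 2 lower adjusted over the list alone (median 0.54, camera adjusted p = 0.099 and adjusted p = 0.64 with an estimated correlation). Nfatc1, a transcription factor of bulge stem cells, rose 3.20-fold, and Lgr6, a receptor of stem cells above the bulge, rose 2.38-fold. The camera test of this list passed without wild type 2 (adjusted p = 0.017) and with hair genes left out (adjusted p = 0.046).

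**Figure D2:**
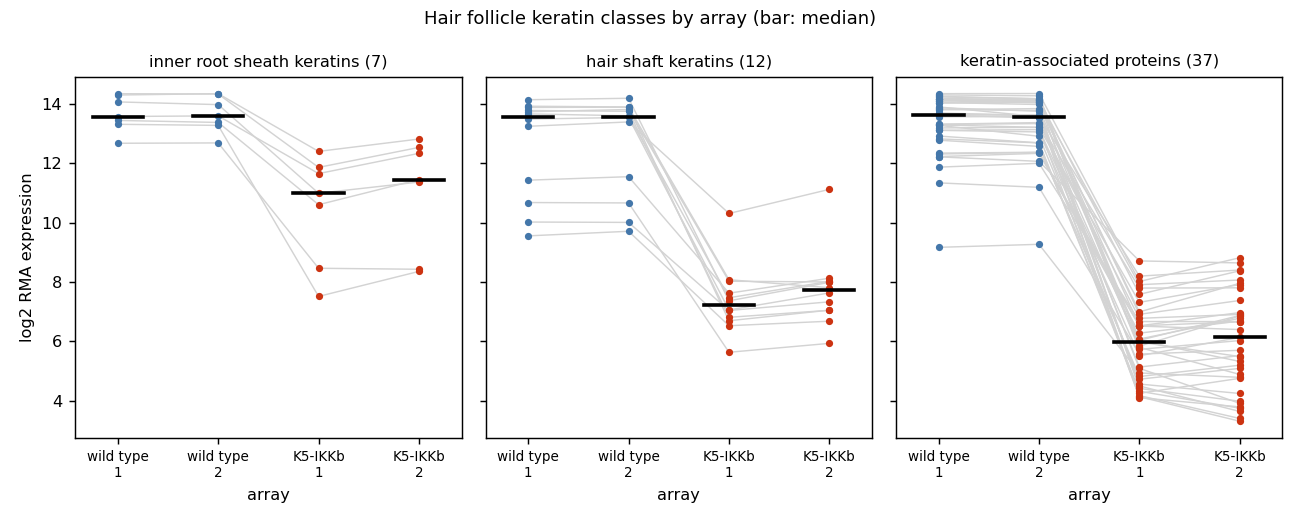
Log2 expression (vertical axes) in each array (horizontal axes) of 7 inner root sheath keratins, 12 hair shaft keratins and 37 Krtap genes; points are genes, grey lines join a gene over the arrays and black bars are medians. The median log2 fold changes were -2.38, -5.82 and -7.36, from wild type medians of 13.58, 13.57 and 13.57.

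Pigment genes were lower as well. In the melanocyte list 13 of 17 tested members fell and 1 rose (14 and 1 adjusted over the list alone), with a median log2 fold change of -1.01 (camera adjusted p = 5.6e-08 and adjusted p = 0.40 with an estimated correlation). Gpnmb, a glycoprotein of melanosomes also made by macrophages, fell 4.57-fold, Gpr143, a receptor of the melanosome membrane, 3.64-fold, and Oca2, a melanosomal transport protein, 3.42-fold. The exception was Rab27a, which carries melanosomes and other secretory vesicles, at 0.62 (adjusted p = 0.011), whose call was lost without wild type 1 (adjusted p = 0.077). Like other members named because 5 or fewer of a list changed in their direction, it was picked after its value was seen unless the fixed rule already named it.

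Interferon-response genes were higher in K5-IKKbeta skin. Of 26 tested interferon-stimulated genes 24 rose and none fell (26 rose adjusted over the list alone), with a median log2 fold change of 1.57 (camera adjusted p = 2.7e-08 and adjusted p = 0.47 with an estimated correlation). Oasl2 rose 11.3-fold, Ifit1, an inhibitor of viral translation, 6.60-fold, and Rtp4, an interferon-induced chaperone of receptors, 6.04-fold. The members short of the threshold were Ifit3, at 1.28 (adjusted p = 0.054), and Mx2, at 0.33 (adjusted p = 0.055). Both passed without K5-IKKbeta 2 (adjusted p = 0.0061 and 0.026), Ifit3 passed without wild type 2 (adjusted p = 0.027), and Mx2 passed with the mean of all probe sets (adjusted p = 0.045). These genes also differed between pools of a genotype. Wild type pool 1 lay below wild type pool 2 in 25 of the 26 genes (median difference -0.56), and K5-IKKbeta pool 1 lay above pool 2 in 26 of 26 (median difference 0.61). All 15 tested interferon-gamma-induced genes rose (15 adjusted over the list alone), with a median of 1.94 (camera adjusted p = 2.7e-08 and adjusted p = 0.41 with an estimated correlation). Among them, Cxcl9 rose 10.6-fold and Cxcl10, a chemokine for activated T cells, 9.69-fold.

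**Figure D3:**
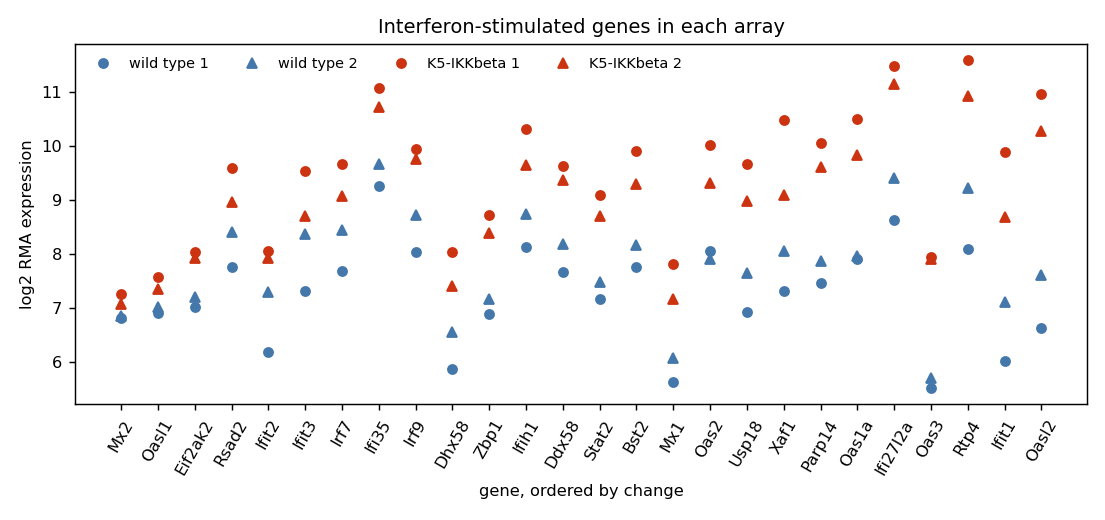
Log2 expression (vertical axis) of the 26 tested interferon-stimulated genes (horizontal axis, ordered by change) in each of the 4 arrays; circles are pool 1 and triangles pool 2 of a genotype. Pool 1 lay below pool 2 in 25 of 26 genes in wild type and above it in 26 of 26 in K5-IKKbeta skin.

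Antigen presentation genes rose in both classes. All 12 tested genes of MHC class I and antigen processing rose (12 adjusted over the list alone, median log2 fold change 1.93, camera adjusted p = 2.7e-08 and adjusted p = 0.40 with an estimated correlation). The immunoproteasome subunits Psmb9 and Psmb8 rose 8.33-fold and 8.10-fold, the peptide transporter Tap2 5.61-fold, and Nlrc5, a transcriptional activator of class I genes, 4.60-fold. In the class II list 9 of 9 rose (9 adjusted over the list alone, median 3.99-fold, camera adjusted p = 2.0e-06 and adjusted p = 0.40 with an estimated correlation). H2-Aa and H2-Eb1, chains of class II molecules, rose 4.77-fold and 4.08-fold, and Cd74, the invariant chain, 4.14-fold.

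NF-kB target genes were mostly higher. Of 25 tested, 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 1.13 (camera adjusted p = 2.0e-06 and adjusted p = 0.45 with an estimated correlation). Ccl2, a chemokine for monocytes, rose 8.75-fold, Icam1, an adhesion molecule for leukocytes, 8.41-fold, Relb, an NF-kB subunit, 6.63-fold, and Tnfaip3, an inhibitor of NF-kB signalling, 5.92-fold. The member that fell was Bcl2l1, a survival protein, at -0.39 (adjusted p = 0.024), a call that was lost without wild type 1 (adjusted p = 0.16), without wild type 2 (adjusted p = 0.10) and with the mean of all probe sets (-0.11, adjusted p = 0.38). Of 9 tested IKK and NF-kB subunits 6 rose (6 adjusted over the list alone, median 0.50, camera adjusted p = 0.0046 and adjusted p = 0.46 with an estimated correlation). Nfkb2 rose 3.32-fold and the IKK-related kinase Ikbke 3.17-fold. The risers include Ikbkb, the gene of the transgene, whose value is also the median of this list. Relb and Nfkb2 are in the list of NF-kB targets too.

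Secreted signals of inflammation rose in part. Among 23 tested chemokines 14 rose and none fell (14 adjusted over the list alone, median log2 fold change 0.80, camera adjusted p = 0.0019 and adjusted p = 0.46 with an estimated correlation), among them Ccl1, a ligand of Ccr8, at 6.46-fold. Of 18 tested cytokines and TNF family ligands 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 0.0036 and adjusted p = 0.40 with an estimated correlation). Ltb, the lymphotoxin beta chain, rose 3.72-fold, the death ligand Tnfsf10 3.57-fold, and Csf1, a growth factor of macrophages, 3.32-fold, while Il1rn, the antagonist of the interleukin-1 receptor, fell (-0.61, adjusted p = 0.0086, and 0.073 without wild type 2). At the 60th percentile the camera call of the cytokine list was lost (median 0.90, adjusted p = 0.090). In the complement list 10 of 11 rose (10 adjusted over the list alone, median 1.12, camera adjusted p = 0.00025 and adjusted p = 0.40 with an estimated correlation), led by the proteases of the classical pathway C1s1 at 3.99-fold and C1ra at 2.37-fold. In the list of apoptosis and death receptor genes 8 of 20 rose and none fell (9 adjusted over the list alone, median 0.33, camera adjusted p = 0.0069 and adjusted p = 0.40 with an estimated correlation). The inflammatory caspase Casp4 rose 5.00-fold, Mlkl, the effector of necroptosis, 2.51-fold, and the initiator caspase Casp8 2.39-fold. The camera call of this list was lost at the 60th percentile (median 0.27, adjusted p = 0.22).

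Markers of several leukocyte types were higher. Of 27 tested macrophage and monocyte genes 20 rose and 2 fell (21 and 2 adjusted over the list alone), with a median log2 fold change of 1.06 (camera adjusted p = 2.1e-05 and adjusted p = 0.40 with an estimated correlation). Mpeg1, a pore-forming protein of macrophages, rose 3.62-fold, Aif1, an actin-binding protein of macrophages, 3.53-fold, and the signalling adaptor Tyrobp 3.29-fold. The members that fell were Arg1, which breaks down arginine, at -2.24, and the lysosomal protease Ctsb, at -0.60, whose call was lost without wild type 1 (adjusted p = 0.052) and without wild type 2 (adjusted p = 0.051). Of 8 tested mast cell, basophil and eosinophil genes 6 rose (6 higher and 1 lower adjusted over the list alone, median 1.15, camera adjusted p = 0.018 and adjusted p = 0.40 with an estimated correlation), including the mast cell proteases Mcpt2 at 3.72-fold, Mcpt4 at 3.42-fold and Cpa3 at 3.35-fold. The camera call was lost with no filter on dim probe sets (median 0.19, adjusted p = 0.057) and with a filter at the 60th percentile (median 1.45, adjusted p = 0.060). Of 14 tested dendritic and Langerhans cell genes 7 rose (7 adjusted over the list alone, median 0.35, camera adjusted p = 0.030 and adjusted p = 0.41 with an estimated correlation). Itgax, an integrin of dendritic cells, rose 3.89-fold and Cd207, a lectin of Langerhans cells, 3.45-fold; the camera call was lost without wild type 2 (adjusted p = 0.064), without K5-IKKbeta 2 (adjusted p = 0.055) and at the 60th percentile (adjusted p = 0.45). Of 5 tested NK and cytotoxic cell genes 4 rose (4 adjusted over the list alone, median 0.77, camera adjusted p = 0.022 and adjusted p = 0.40 with an estimated correlation), led by the granzyme Gzmc at 7.81-fold. The others were Nkg7, Ccl5 and Klrk1, whose calls were lost without wild type 1 for Nkg7 (adjusted p = 0.051) and without wild type 2 for Ccl5 (adjusted p = 0.053) and Klrk1 (adjusted p = 0.062).

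Lymphocyte and neutrophil lists did not pass camera as sets, and the T cell list depended on the setting. Of 13 tested T cell genes 6 rose and none fell (6 adjusted over the list alone, median log2 fold change 0.40, camera adjusted p = 0.11 and adjusted p = 0.61 with an estimated correlation). Il7r, the receptor of interleukin-7, rose 3.04-fold, Thy1, which fibroblasts also make, 2.78-fold, and Cd3g, a chain of the T cell receptor complex, 2.24-fold. The T cell list passed without wild type 1 (adjusted p = 0.020), without K5-IKKbeta 2 (adjusted p = 0.039), with no filter on dim probe sets (adjusted p = 0.013), with the mean of all probe sets (adjusted p = 0.022) and with hair genes left out (adjusted p = 0.034), and at the 60th percentile its median was -0.13 (adjusted p = 0.98). Of 10 tested neutrophil genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.20, fry adjusted p = 0.020 and adjusted p = 0.61 with an estimated correlation). The risers were Lcn2, which binds bacterial siderophores, at 8.92-fold, the alarmin S100a9 at 5.49-fold, Fpr2 and Mmp9, and Stfa2l1 fell. Mmp9 lost its call without wild type 1 (adjusted p = 0.075) and without wild type 2 (adjusted p = 0.12), and keratinocytes also make Lcn2 and S100a9. Of 8 tested B and plasma cell genes 2 rose, Fcer2a and Blnk, and 2 fell, Prdm1 and Sdc1 (3 and 2 adjusted over the list alone, camera adjusted p = 0.90 and adjusted p = 0.95 with an estimated correlation). For that list the median of 0.16 and the mean of 0.10 were above 0 while the camera test pointed down. Prdm1 and Sdc1 are also expressed by keratinocytes.

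Genes of the epidermal lists moved in both directions. Whole skin was measured, so for genes made in both, changes in epidermis and in follicles cannot be told apart. In the list of stress keratins and alarm genes 9 of 16 rose and 5 fell (9 and 5 adjusted over the list alone, median log2 fold change 1.02, camera adjusted p = 0.36, fry adjusted p = 0.020 and adjusted p = 0.79 with an estimated correlation). Stfa3 rose 10.1-fold, Krt16, a keratin induced in injured epidermis, 9.34-fold and Lcn2 8.92-fold. The members that fell were the cornified envelope precursors Sprr2h (-2.61), Sprr1b (-2.41) and Sprr1a (-1.85), the crosslinking enzyme Tgm1 (-1.31) and the keratin Krt6a (-0.78). The call of Krt6a was lost without wild type 1 (adjusted p = 0.064) and without wild type 2 (adjusted p = 0.057). Of 27 tested genes of the cornified envelope and terminal differentiation 14 rose and 7 fell (15 and 8 adjusted over the list alone, median 0.63, camera adjusted p = 0.76 and adjusted p = 0.95 with an estimated correlation). Krt2 was at least 20.9-fold higher, while Tgm3, a transglutaminase of epidermis and hair, fell 6.10-fold, Casp14, a protease of cornification, 3.62-fold, and the envelope protein Ivl 3.35-fold. Of 16 tested basal keratinocyte and hemidesmosome genes 10 rose and none fell (11 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 0.043 and adjusted p = 0.54 with an estimated correlation). Col7a1, the collagen of anchoring fibrils, rose 2.58-fold and Lamb3, a laminin chain of the basement membrane, 2.20-fold; the camera call was lost without wild type 2 (adjusted p = 0.076) and at the 60th percentile (adjusted p = 0.077). Values of single Sprr and Stfa genes are uncertain because these families hold near-identical copies.

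Neither cell cycle list passed camera over all arrays. Of 29 tested proliferation genes only the replication helicase subunit Mcm6 rose (0.62, adjusted p = 0.011) and none passed adjusted over the list alone (0 genes, median log2 fold change 0.16, camera adjusted p = 0.59 and adjusted p = 0.95 with an estimated correlation). The call of Mcm6 was lost without wild type 1 (0.49, adjusted p = 0.079) and with the mean of all probe sets (0.37, adjusted p = 0.062), and without K5-IKKbeta 1 the camera test of the list passed (adjusted p = 0.012). Of 18 tested genes of cell cycle arrest and p53 targets 6 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.90 and adjusted p = 0.95 with an estimated correlation). Cyclin G1 (Ccng1) rose 1.69-fold and the kinase inhibitor Cdkn1c 1.66-fold, while the kinase Plk2 (-0.76), Gadd45a (-0.71) and the kinase inhibitor Cdkn1a (-0.57) fell. Plk2 lost its call with the mean of all probe sets (-0.34, adjusted p = 0.086), and Cdkn1a without wild type 1 (adjusted p = 0.11) and without wild type 2 (adjusted p = 0.10). The median of this list, 0.05, and its mean, 0.07, were above 0 while the camera test pointed down.

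Lipid genes were higher. Of 10 tested sebaceous gland genes 9 rose (9 adjusted over the list alone), with a median log2 fold change of 1.70 (camera adjusted p = 1.2e-05 and adjusted p = 0.40 with an estimated correlation). Far2, which makes fatty alcohols, rose 8.54-fold, the lipid droplet protein Cidea 7.60-fold, the fatty acid desaturase Scd3 6.97-fold and the fatty acid hydroxylase Fa2h 5.55-fold. In the list of cholesterol and fatty acid synthesis 13 of 22 rose and none fell (14 adjusted over the list alone, median 0.59, camera adjusted p = 0.00062 and adjusted p = 0.46 with an estimated correlation). The fatty acid elongases Elovl6 and Elovl4 rose 3.94-fold and 2.94-fold. In the adipocyte list 10 of 17 rose and none fell (12 adjusted over the list alone, median 0.69, camera adjusted p = 0.0018 and adjusted p = 0.46 with an estimated correlation). The adipocyte members with the largest rises, Cidea, the nuclear receptor Pparg at 3.60-fold, the desaturase Scd1 at 2.32-fold and the fatty acid synthase Fasn at 2.03-fold, are expressed by sebaceous glands too. Leptin (Lep) and Fabp4, adipocyte genes picked after their values were seen, did not pass the threshold (-0.12, adjusted p = 0.73, and 0.028, adjusted p = 0.87). They were 2 of the 7 tested adipocyte members that did not pass, so they do not stand for the list. Neither had a stable sign, with Lep at 0.19 without wild type 1 and 0.076 without K5-IKKbeta 2, and Fabp4 at -0.073 without K5-IKKbeta 2 and -0.31 with the mean of its probe sets.

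Genes of the dermis and deeper tissues rose as well. Of 24 tested fibroblast and collagen genes 21 rose and none fell (22 adjusted over the list alone), with a median log2 fold change of 1.07 (camera adjusted p = 5.6e-08 and adjusted p = 0.47 with an estimated correlation). Twist2, a transcription factor of dermal fibroblasts, rose 2.87-fold, the filament protein Vim 2.75-fold and the collagen chain Col6a3 2.62-fold. Of 20 tested skeletal muscle genes 17 rose and none fell (20 adjusted over the list alone, median 0.94, camera adjusted p = 9.8e-07 and adjusted p = 0.45 with an estimated correlation). Actn3, an actinin of fast muscle fibres, rose 2.41-fold and the troponin Tnnt3 2.24-fold. Of 17 tested endothelial genes 11 rose and none fell (13 adjusted over the list alone, median 0.56, camera adjusted p = 0.00060 and adjusted p = 0.40 with an estimated correlation), including Vwf, a clotting protein of endothelium, at 2.12-fold and the adhesion molecule Pecam1 at 2.01-fold. In the list of matrix proteases and tissue remodelling 13 of 18 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.61, camera adjusted p = 0.0029 and adjusted p = 0.40 with an estimated correlation). The macrophage elastase Mmp12 rose 2.99-fold and the matrix protease Mmp11 2.31-fold, and Cst6, a cysteine protease inhibitor of epidermis and hair, fell (-0.49, adjusted p = 0.030). For the matrix protease list the camera call was lost at the 60th percentile (median 0.52, adjusted p = 0.11). The call of Cst6 was lost without wild type 1 (adjusted p = 0.15), wild type 2 (adjusted p = 0.13) or K5-IKKbeta 2 (adjusted p = 0.062). Of 11 tested Schwann cell and nerve genes 4 rose and 2 fell (4 and 3 adjusted over the list alone, median 0.13, camera adjusted p = 0.90 and adjusted p = 0.95 with an estimated correlation), with the myelin proteins Pmp22 and Mbp each 2.27-fold higher and Gfra3, a receptor of sensory neurons (-0.43), and the transcription factor Egr2 (-0.58) lower. Gfra3 lost its call without wild type 1 (adjusted p = 0.15) and without wild type 2 (adjusted p = 0.079), and Egr2 without wild type 2 (adjusted p = 0.054). All 3 tested red blood cell genes changed (3 adjusted over the list alone), with the anion exchanger Slc4a1 (-1.88) and Bpgm (-1.18) lower and the haem synthesis enzyme Alas2 (0.66) higher (median -1.18, camera adjusted p = 0.14, fry adjusted p = 0.014 and adjusted p = 0.46 with an estimated correlation).

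**Figure D4:**
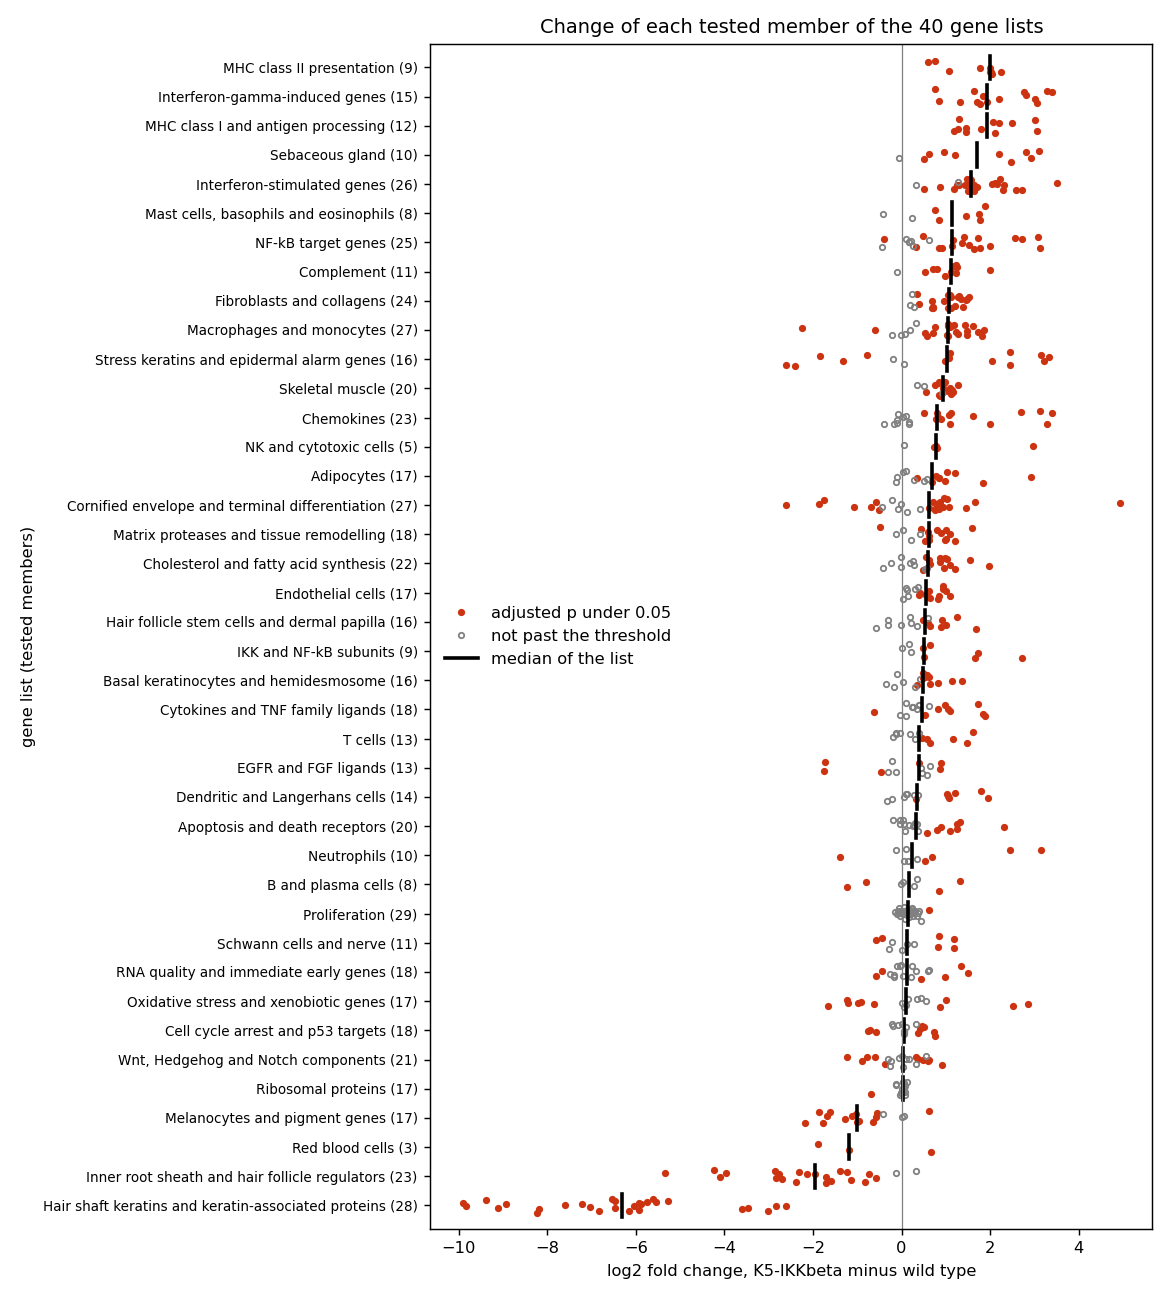
Log2 fold change of K5-IKKbeta against wild type skin (horizontal axis) for every tested member of the 40 gene lists (vertical axis, number of tested members in parentheses); filled points passed an adjusted p of 0.05 over all genes, open points did not, and black bars are list medians. The hair shaft list lies lowest, with a median of -6.32, and the MHC class II list highest, with a median of 3.99-fold.

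Signalling and stress lists had members in both directions and did not pass as sets. Of 21 tested Wnt, Hedgehog and Notch components 6 rose and 5 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.58 and adjusted p = 0.79 with an estimated correlation). Gli1 and Ptch1, both targets of hedgehog signalling, rose 1.87-fold and 1.39-fold; Ptch1 was picked after its value was seen, and its call was lost without wild type 1 (adjusted p = 0.10) and without wild type 2 (adjusted p = 0.062). Lef1, a transcription factor of Wnt signalling, was at -1.24 (adjusted p = 0.011), a call that was lost without wild type 2 (-1.04, adjusted p = 0.074). Also lower were Wnt3a (-0.60) and the Notch targets Heyl (-0.89), whose call was lost without wild type 2 (adjusted p = 0.0502), and Hes1 (-0.36). Hes1 lost its call without wild type 1 (adjusted p = 0.12), wild type 2 (adjusted p = 0.25) or K5-IKKbeta 1 (adjusted p = 0.13), and so did Wnt5a (-0.78), with 0.084, 0.21 and 0.059. With no filter both calls were lost (adjusted p = 0.069 for Hes1 and 0.052 for Wnt5a). The median of the list was 0.04 and its mean -0.01, with the camera test pointing down. Of 13 tested EGFR and FGF ligands 3 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.50 and adjusted p = 0.79 with an estimated correlation). Fgf22 and the EGFR ligand Tgfa fell 3.36-fold and 3.33-fold, Hbegf fell (-0.46), and Egf (0.86), Pdgfa (0.40) and Epgn (0.89) rose. Without wild type 1 the calls of Epgn (adjusted p = 0.059), Hbegf (0.13) and Pdgfa (0.17) were lost, without wild type 2 those of Epgn (0.069), Hbegf (0.11) and Pdgfa (0.085), and without K5-IKKbeta 2 that of Hbegf (0.054). That list had a median of 0.40 and a mean of -0.02, and its camera test pointed down. Of 17 tested oxidative stress and xenobiotic genes 4 rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.50 and adjusted p = 0.79 with an estimated correlation). The aldehyde dehydrogenase Aldh3a1 rose 7.24-fold and the cytochrome Cyp1a1, a target of the aryl hydrocarbon receptor, 5.74-fold, Gsta4 (1.01) and Gpx1 (0.87) rose too, while the glutathione peroxidase Gpx2 fell 3.18-fold and Gclc, of glutathione synthesis, 2.34-fold. Its median of 0.10 and mean of 0.13 were above 0 with a camera test pointing down.

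Of 17 tested ribosomal protein genes none rose and 1 fell, Rps6 (-0.70, adjusted p = 0.030), and none passed adjusted over the list alone (0 genes, camera adjusted p = 0.45 and adjusted p = 0.79 with an estimated correlation). Rps6 lost its call without wild type 1 (adjusted p = 0.14), without wild type 2 (adjusted p = 0.11) and with the replicate block (adjusted p = 0.051). The median of this list was 0.03 and its mean -0.02, with the camera test pointing down. In the list of immediate early and handling-related genes, which also serves as a check of RNA quality, 4 of 18 rose and 2 fell (4 and 2 adjusted over the list alone, median log2 fold change 0.12, camera adjusted p = 0.90 and adjusted p = 0.95 with an estimated correlation). The phosphatase Dusp1 rose 2.82-fold, the transcription factor Fos 2.54-fold, Atf3 1.99-fold and the chaperone Dnajb1 by 0.44 on the log2 scale. Egr3 fell (-0.45), as did Egr2 (-0.58), whose call was lost without wild type 2 (adjusted p = 0.054). Egr3 and Dnajb1 lost their calls without wild type 1 (adjusted p = 0.090 and 0.12), wild type 2 (0.15 and 0.21) or K5-IKKbeta 1 (0.059 and 0.11), and Dnajb1 also after another quantile normalization (0.086), median centring (0.052), leaving out hair genes (0.11) or with no filter (0.056). With the mean of all probe sets Egr3 was at -0.27 (adjusted p = 0.054).

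By camera with its preset correlation of 0.01, 22 of the 40 lists were higher and 3 lower. None passed with a correlation estimated from the 2 residual degrees of freedom (0 lists). That setting has little power, since its test also rests on 2 degrees of freedom. The MHC class II list stood at adjusted p = 0.40 there, although its estimated correlation of -0.063 lay below the preset. The setting therefore cannot tell whether correlation undoes a call. Fry tests whether genes of a set move one way on balance without comparing them with other genes. By fry, 24 lists were higher and 4 lower. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333. Without limma's pooling of the spread across genes 80 genes were higher and 54 lower.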

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

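Tests first described in this part were all chosen after the results were seen. List counts, camera values and the settings that leave out an array were planned, but which of them are shown here was chosen afterwards. Probe sets that had no single gene name in the annotation used here were outside the comparison, and a signal appeared there: of 3977 bright enough to test, 427 were higher and 298 lower in K5-IKKbeta skin (limma, Benjamini-Hochberg adjusted). The largest rise was 1418536_at, from 8.87 to 12.25 on the log2 scale (log2 fold change 3.39), and the largest fall was 1451859_at, from 13.79 to 4.63, a value near background, so its size is not exact.

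Hair shaft genes fell with a median log2 fold change of -6.32. A larger share of resting follicles stays open. Shh, made by the bulb of growing follicles, did not fall (log2 fold change 0.32, 95% interval 0.02 to 0.62). Its value was 0.46 without K5-IKKbeta 1 and 0.18 without K5-IKKbeta 2. Of 29 proliferation genes 1 was higher and 0 lower (median 0.16), and the hedgehog targets Gli1 (0.91) and Ptch1 (0.48) rose. But 21 of 23 members of the list that holds Shh fell, Lef1 among them (-1.24, and -1.04 without wild type 2). These values point both ways, and the falls in that list are part of the pattern to be explained. Inner root sheath keratins fell, but their median in K5-IKKbeta skin was still 11.17. The 75th percentiles of those arrays were 8.66 and 8.69, which Krt26 and Krt72 did not reach. As far as resting follicles do not make these keratins, that median argues against rest of every follicle. It does not tell what share rested. A loss of whole follicles is argued against by the follicle stem cell and dermal papilla list, whose median was 0.54 (bootstrap 95% interval 0.17 to 0.90), although several of its genes are also made outside follicles and the interval takes genes as independent. Follicles at an earlier stage of growth and a block of shaft differentiation cannot be told apart here and both stay open. The fall grew from inner root sheath keratins (median -2.38) to shaft keratins (-5.82) to Krtap genes (-7.36), with Spearman's rho at 0.63 across genes. That order decides nothing, since the wild type medians of 13.57 and 13.58 lie above the 99th percentile of the arrays (12.59), where saturation may set the size of a fall.

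Interferon and antigen presentation genes rose together while hair transcripts were lost. Hair genes held 6.20% and 5.88% of the summed linear signal of tested genes in wild type and 0.30% and 0.42% in K5-IKKbeta arrays, a loss that would raise every other gene by 0.085 on the log2 scale. The lower quartiles of the interferon-stimulated, MHC class I and MHC class II lists were 1.34, 1.41 and 1.08. Dilution of 0.085 is too small for these, as far as array signals are linear. Saturation may hold down the wild type signal of the brightest hair genes, so 0.085 may be too low. By how much was not tested. Whether a lower share of follicle cells raised all other cell types alike stays open. The lists of fibroblasts, muscle, endothelium, adipocytes and nerve differed (permutation p = 0.00068, Kruskal-Wallis statistic over 5 lists), but that test takes genes as independent, and the estimated correlation among fibroblast genes was 0.84. Fibroblast and endothelial values overlap (lower quartile 0.69 and upper quartile 0.84), and the nerve list did not rise as a set (4 up and 2 down, camera adjusted p = 0.90). A response of the skin to the transgene and a change in cell makeup or in the depth of the skin piece stay open as hypotheses.

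Interferon-stimulated genes also differed between pools of a genotype. The median difference was 0.61 between K5-IKKbeta pools 1 and 2 and -0.56 between the wild type pools. Both lay outside the middle 95% of 10000 random lists of like size and expression (-0.09 to 0.09 and -0.11 to 0.03). A shift shared by all genes of an array was not put to the test by this, since RMA had normalized the arrays by quantiles. Other lists split the pools as well: 20 of 40 lay outside such a range between the K5-IKKbeta pools and 18 between the wild type pools, although genes of a list are not independent as random genes are. Between the K5-IKKbeta pools the medians were -0.32 for proliferation (29 of 29 lower in pool 1), -0.22 for fibroblasts (24 of 24), -0.40 for the inner root sheath and 0.40 for the cornified envelope. Differences among the mice or cages of a pool, the skin piece or a batch of labelling or hybridisation may lie behind these splits and were not tested. With the pools so far apart, the size of the rise is less certain for these genes than for the MHC class II list, whose pools differed by -0.02 and 0.01.

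Of the 3 splits of the 4 arrays into 2 and 2, 1 gave as many changed genes as the real grouping, which was that grouping itself. It gave 4436, against 0 for the highest other. Each other split puts 1 array of each genotype in each group, so a genotype difference counts as spread there and few calls follow by design. Also, 3 splits are too few for a share under 0.05.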

How the results depend on the processing

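Ikbkb stayed higher in every setting, and no result past the threshold reversed. Ikbkb is read here from its brightest probe set, or from the mean of its probe sets in that setting. Probe set 1454184_a_at, which rose from 6.52 to 8.76, was not put through these settings alone, so they do not test its rise. Without moderation across genes 80 genes were higher, 54 lower and 81 changed at least 2-fold, and Ikbkb (0.50) had an adjusted p of 0.18; with 2 residual degrees of freedom per gene this test has little power. Against a 1.2-fold change (treat), 1608 were higher and 740 lower, and Ikbkb (0.50) had an adjusted p of 0.19. Neither setting gives a list test. With an estimated correlation camera called 0 lists higher and 0 lower, but at 2 residual degrees of freedom that test has little power too. With hair genes left out before a new quantile normalization, added after the data were seen, 1 list was lower in place of 3, because both hair lists were removed. Leaving out 1 array at a time, with a lone array assumed to vary like the other group, gave 1570 to 3096 higher genes, 669 to 1544 lower genes and an Ikbkb log2 fold change of 0.40 to 0.61, no longer past the threshold without either wild type array. Sample number alone does not explain that loss, since without a K5-IKKbeta array 4378 and 4640 genes changed and Ikbkb passed (adjusted p of 0.048 and 0.010). By construction the spread then comes from the other group alone, and the K5-IKKbeta pools differed more (SD of the difference 0.26) than the wild type pools (0.20); whether this was the cause was not tested. Of 196 named genes, Ikbkb included, 178 lost their call without moderation, 27 without wild type 2, 26 without wild type 1, 21 with treat, 5 with the mean of all probe sets (Plk2 among them), 4 without K5-IKKbeta 1, 3 with no filter and 2 without K5-IKKbeta 2. The 196 include Shh, Gata3, Ifit3, Mx2, Lep and Fabp4, which had not passed and so had no call to lose. Dnajb1 alone lost its call after another quantile normalization, median centring or leaving out hair genes, and Rps6 alone with the replicate block. The cause was not tested. A filter at the 60th percentile, which tests fewer genes, ended 6 list calls (cytokines, basal keratinocytes, apoptosis, dendritic cells, mast cells, matrix proteases). The mast cell call was also lost with no filter. For 28 values, 21 of lists and 7 of genes, past the threshold in neither setting, the sign or the direction of the test differed. List medians there were 0.048 for p53 targets with no filter and 0.055 with fry, 0.056 for stress keratins and -0.13 for T cells at the 60th percentile, 0.088 for nerve with the mean of probe sets, 0.13 for B cells after another quantile normalization and 0.16 with fry, and 0.038 for Wnt components and 0.033 for ribosomal proteins with fry. With hair genes left out B cells were at 0.081 and immediate early genes at -0.027. Fabp4 was at -0.31 with the mean of probe sets, -0.012 after centring and -0.068 with hair genes left out. Over the left-out arrays the ranges were -0.30 to 0.030 for Gata3, -0.43 to 0.19 for Lep, -0.073 to 0.13 for Fabp4, 0.51 to 0.73 for the cornified envelope, -0.051 to 0.33 for proliferation, -0.056 to 0.16 for p53 targets, 0.039 to 0.22 for B cells, -0.027 to 0.27 for nerve, -0.040 to 0.35 for EGFR and FGF ligands and -0.0034 to 0.13 for immediate early genes. Same-numbered arrays share only a number; the correlation of their differences over genes was 0.25, and with a replicate block 3088 genes were higher and 1465 lower, 22 lists were higher and 3 lower, and Ikbkb (0.50) had an adjusted p of 0.048. Low signal limits what can be said of the 5120 genes removed as dim.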

Other observations

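Families of genes that share a symbol stem were tested after the data were seen (208 families of at least 8 tested genes, camera at its preset correlation, limma). Of these, 8 passed: Krtap (median log2 fold change -7.36) and Krt (-1.45), which hold hair genes, Eif (-0.14, 13 lower and 5 higher), Irf (0.60, 7 higher), Ccl (0.81, 11 higher) and the 3 described here. Of the Krt genes 27 were lower and 10 higher. With hair genes left out before a new quantile normalization, the 23 remaining Krt genes had a median of 0.12, with 8 higher and 8 lower. For Eif, Irf, Ccl and the retinol dehydrogenase and Parp families the adjusted p was 0.04998, and no family passed with an estimated correlation. Claudins, the sealing proteins of tight junctions, were lower: 6 of 11 fell and 1 rose, with a median log2 fold change of -0.53 (adjusted p = 0.049; adjusted p = 0.99 with an estimated correlation). Cldn8 (-2.14) and Cldn4 (-2.03) fell most, and the riser was Cldn5 (0.56), the claudin of endothelium, whose call was lost without wild type 1 (adjusted p = 0.060). Under another quantile normalization, median centring and the setting without hair genes the median stayed between -0.57 and -0.63, with 6 or 7 falling.

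Retinol dehydrogenases, which interconvert retinol and retinal, were higher: 6 of 8 rose and none fell, with a median log2 fold change of 0.67 (adjusted p = 0.04998; adjusted p = 0.99 with an estimated correlation), led by Rdh9 (1.68), Rdh11 (1.63) and Rdh1 (1.48). Of 11 genes with the stem Parp, 5 rose, among them Parp14 (2.16), Parp9 (1.77) and Parp12 (1.72), which interferon is known to induce (median 0.33, adjusted p = 0.04998; adjusted p = 0.99 with an estimated correlation). Under the 3 other scalings both medians stayed above 0, at 0.57 to 0.63 for retinol dehydrogenases and 0.24 to 0.29 for Parp genes, with 5 of 8 and 4 of 11 genes higher in each.

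The signal of the 3' end of Gapdh minus that of its 5' end, a measure of RNA integrity, was -0.12 and -0.13 in wild type and -0.02 and -0.06 in K5-IKKbeta arrays on the log2 scale. For Actb it was 0.36 and 0.33 against 0.32 and 0.29. Over 18 hybridisation controls the median difference between groups was 0.08 and the largest 0.19.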
